A study of Homo sapiens with 2 samples.

How the data were processed

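The data were 2 RNA sequencing libraries of NCI-N87 xenograft tumours, 1 untreated and 1 treated with trastuzumab plus pertuzumab. Per the labels' protocols, tumours were kept in an RNA-preserving solution, RNA was extracted with a column kit, and 3 µg from each of 5 animals per group were mixed to 15 µg before the libraries were prepared with a stranded mRNA kit. The group of each library was taken from its treatment label, and no independent check of the labels' direction was possible. Pooling leaves 1 value per group, so animals cannot be compared.

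Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.5.3a and edgeR 3.26.8 were used, with the human builds GRCh37 and hg19. The gene counter, the annotation release, the use of strand in counting and the treatment of mouse reads are not given in the sources used here. The deposited table has 27339 rows with gene symbols, Entrez identifiers, hg19 positions and transcript widths. The authors' expected counts per gene are estimated counts that need not be whole: 63.7% of the nonzero values in the untreated library and 73.7% in the treated library were whole within 0.001. Fractions arise where reads are divided among overlapping or similar genes, so such genes are less certain. The authors' FPKM values in the deposited table equal count per kilobase of transcript width, scaled to a total that was 1.18 and 1.19 times the sum of the counts. The authors' log2 fold changes, log2 mean CPM, p-values and adjusted p-values are in the same deposited table, and the spread assumed for those p-values is not given in the sources used here. With edgeR's exact test and an assumed dispersion of 0.2 on the unrounded counts, 927 genes had an adjusted p under 0.05, against 929 in the authors' deposited table, and the largest difference in p was 0.0176.

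For the values reported here the expected counts were rounded to whole numbers. The totals were 115767539 counts in the untreated library and 77433516 in the treated library, and the 10 most abundant genes took 4.82% and 4.83% of them. CPM were computed on totals scaled by the TMM factors of edgeR 4.0.16, which were 0.992 and 1.01. The log2 ratio of treated over untreated was computed with 0.5 counts added to each library, and folds printed with a gene are this ratio on the linear scale. A gene was measured if it had at least 1 CPM in 1 library, and 13744 genes were. It was called higher or lower if it was at least 2-fold apart and the exact 95% Clopper-Pearson interval of its ratio, from the binomial share of its counts in the 2 libraries, excluded no difference. For a gene with 0 counts the fold is a bound against 3 counts in that library, 0.0261 CPM untreated and 0.0384 CPM treated. Intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules, and they leave out differences between animals, pools and library preparations.

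Before the data were examined, 41 gene lists were fixed, covering HER family receptors and ligands, signalling outputs, epithelial types, immune and stress genes, metabolism, basic cell functions and host cell types. For each list the measured members, the numbers called and the median log2 ratio were taken, and the median was placed among those of 10000 random lists of the same size matched in 20 bins of mean expression. Lists with fewer than 3 measured members got no percentile. List medians with genes of 0 counts set at their bound were equal to those printed. Lists overlap in some members. Genes were named by a rule also fixed then: the 4 HER family receptors, the 12 largest and 12 smallest log2 ratios among called genes of at least 10 CPM in the higher library with an established symbol, up to 2 members at each end of each list, and the 5 most abundant genes of each library. Genes named outside that rule are stated to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

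For the account of neighbouring genes, 13300 measured genes on assembled chromosomes, without Y and without rows of repeated loci, were ordered by hg19 start and divided into 532 blocks of 25. Their medians were set against the lowest and highest block medians in 100 random orders. Runs were also chosen on every second gene and measured on the genes between them, in both ways of splitting, without genes that share both counts with another. Positions are those of the deposited table. Transcript GC content came from GENCODE annotation of GRCh38, matched by gene identifier or symbol for 98.9% of the block genes, and no position of that build is used. The table has 1069 rows of repeated loci, and 3063 rows with counts above 0 share both counts with another row.

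The calculations were tested on simulated counts of 13317 genes drawn from the 2 libraries' means. Known folds, all past the 2-fold threshold, were given to 200 genes. All 200 were called on the right side, 0 of 13117 unchanged genes were called, and 95.3% of the intervals held the true ratio. Of 200 unshifted simulated lists, 5% lay beyond percentiles 2.5 and 97.5. These lists were drawn at random from the same ratios as their comparison lists. The share was therefore set by construction and does not cover lists whose genes move together. The simulation holds counting error only. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, were used. Alternatives were library totals, DESeq2 size factors and upper quartiles in place of TMM, no minimum CPM or 5 CPM, 2 or 5 added counts, other fold thresholds and interval rules, the genes of host lists left out, list means, and 10 expression bins. The list of mitochondrially encoded genes had 0 rows in the table, so the planned totals without them were not run.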

Results

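Bulk RNA sequencing was used to compare untreated tumours of NCI-N87 with tumours that had become refractory to a pair of antibodies. NCI-N87 is an established human gastric cancer cell line that carries an amplified ERBB2 gene, which encodes the receptor HER2, and it was grown under the skin of nude mice. Trastuzumab and pertuzumab are antibodies that bind different parts of the extracellular region of HER2, and each was injected weekly at 20 mg/kg for 12 weeks. There were 2 libraries, 1 per group, and each was made from a pool of equal amounts of tumour RNA from 5 animals. The comparison addressed how the transcripts of the refractory tumours differed from those of untreated tumours. The untreated library held 115767539 counts and the treated library 77433516. With 1 library per group no difference has a replicate check, no call rests on a p-value, and the spread between animals could not be seen. Genes are called higher or lower in the treated pool by a rule of size, and the 95% intervals given with log2 ratios are exact and cover counting error only.

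The treated pool had more transcript of most of the measured intestinal and gastric epithelial genes. It had less of squamous epithelial genes, interferon-stimulated genes and targets of the MAPK, WNT and TGF-beta pathways. ERBB2 was abundant in both pools and was 1.46-fold higher in the treated pool. Proliferation genes differed little between the pools. Among 13744 measured genes, those with at least 1 CPM (counts scaled to the library total) in 1 library, 1125 were at least 2-fold higher and 1609 at least 2-fold lower in the treated pool. The lower genes made up 58.9% of the 2734 called genes. Another 8926 genes, 64.9% of those measured, lay within 1.5-fold. Large differences were more often towards lower values, with 117 genes at least 8-fold higher and 495 at least 8-fold lower. Of the gene lists fixed before the data were examined, 40 had enough measured members. Among these, 21 had a median log2 ratio beyond the central 95% of random lists matched on expression. About 2 would lie there if the genes of a list varied independently. Genes of a list can move together and lists share members, so chance can give more than 2, and how many was not estimated. Block-centred medians are medians after each gene's ratio was centred on its block of 25 neighbouring genes. These percentiles describe the 2 libraries and are not tests between the conditions.

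**Figure D1:**
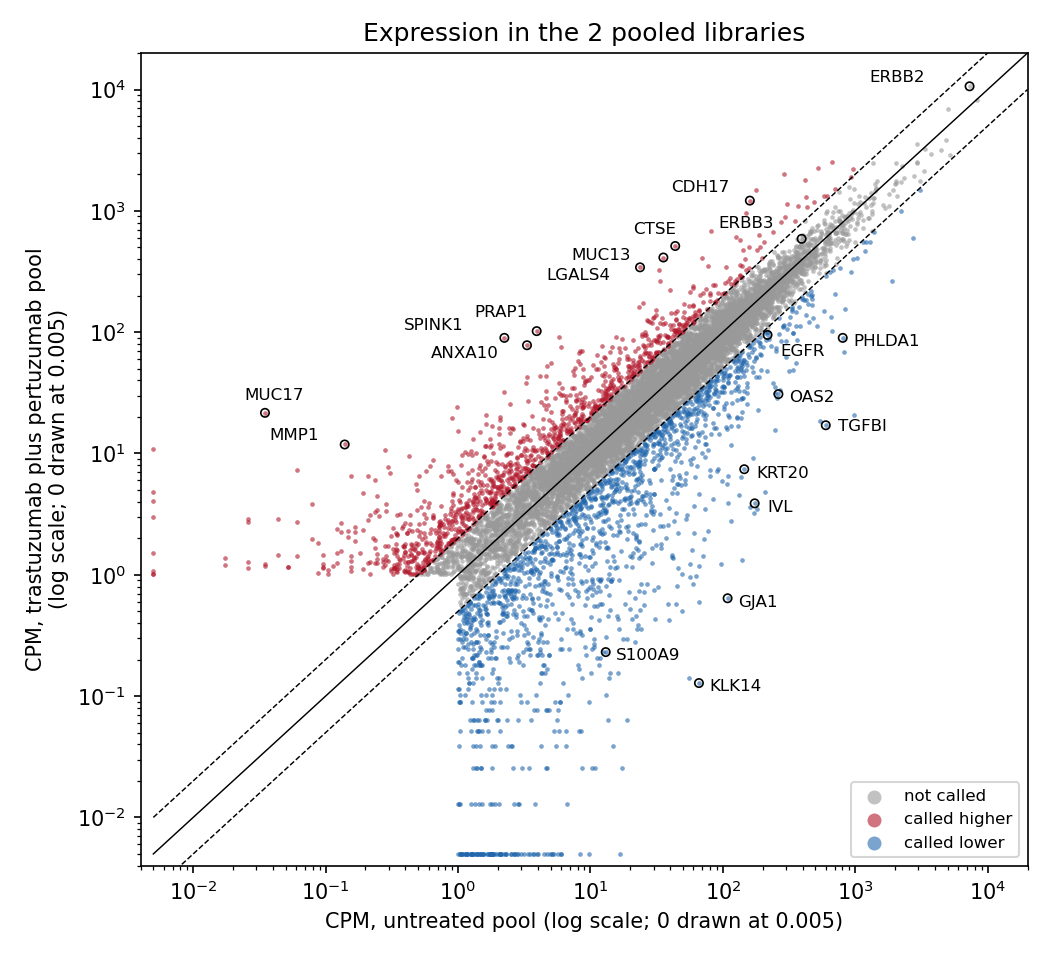
Each point is 1 of the 13744 measured genes, with its CPM in the untreated pool on the x axis and in the trastuzumab plus pertuzumab pool on the y axis, both on log scales with 0 drawn at 0.005. The solid line marks equal CPM and the dashed lines 2-fold, red points are the 1125 genes called higher and blue points the 1609 called lower, and the circled genes are named in the text.

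ERBB2, ERBB3 and EGFR were expressed in both pools, and ERBB4 was not detected. ERBB2 (Entrez gene 2064, hg19 chromosome 17, 37844337 to 37884915), the target of both antibodies, stood at 7304 CPM untreated and 10632 CPM treated, a log2 ratio of 0.54 (interval 0.54 to 0.55). It took 0.724% of all counts in the untreated library and 1.07% in the treated library. ERBB3, the partner of HER2 in ligand-driven dimers, stood at 394 and 588 CPM, a log2 ratio of 0.58 (0.56 to 0.60). EGFR (chromosome 7, 55086725 to 55275031) was the only one of these receptors past the 2-fold rule, 2.29-fold lower at 218 CPM untreated and 94.9 CPM treated. ERBB4 had 0 counts in both libraries, which allows up to 0.0261 CPM untreated and 0.0384 CPM treated. The 3 measured receptors had a median log2 ratio of 0.54 (block-centred 0.34) and, with EGFR among them, a mean of -0.03. Among 7 measured ERBB ligands, 1 was called higher and 2 lower, with a median of -0.76 at percentile 1.84 (block-centred -0.57) and a mean of -1.27 at percentile 4.12. AREG (amphiregulin) had a log2 ratio of 1.09, while NRG4 (neuregulin 4) stood at -1.44. EGF was at 3.03 CPM untreated and had 2 counts in the treated library, a log2 ratio of -6.57 (-9.94 to -5.02).

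Genes beside ERBB2 at 17q12-q21 moved unequally. Of 13 measured members, ERBB2 included, 5 were called higher and 1 lower, and their median of 0.54 (block-centred 0.34) lay at percentile 99.9. PPP1R1B (DARPP-32) went from 671 to 2532 CPM, a log2 ratio of 1.92, and GSDMB, which encodes gasdermin B, had a log2 ratio of 2.12. CDK12 stood at -0.13, and PNMT, expressed at 2.54 CPM untreated, was called lower at -3.02. Among 18 measured receptor tyrosine kinases outside the HER family, 5 were called higher and 4 lower, with a median of 0.16 (percentile 88.9, block-centred 0.05) and a mean of -0.17. FGFR3 had a log2 ratio of 1.98, from 24.7 to 97.4 CPM, and AXL one of 1.95, from 1.90 to 7.36 CPM. FGFR3 lies in a stretch of chromosome 4 whose genes were on the whole higher in the treated pool, which is described with the neighbouring genes. NTRK2, the receptor for BDNF, was 27.1-fold lower, and EPHA4 was 9.46-fold lower.

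Intestinal epithelial markers were the list with the largest positive median. Of the 28 genes in that list 15 were measured, and 11 were called higher and 0 lower in the treated pool. Their median log2 ratio was 2.92 at percentile 100. With a minimum of 5 CPM this median was 0.93 lower, the largest move of any list median under that setting. Among those called higher, FABP2, SI, MEP1A, GUCA2B and ALPI lay at 1.02 to 1.49 CPM treated. They were measured only through that library, and all but FABP2 were chosen after their values were seen. REG4 and GPA33 (0.427 to 9.59 CPM, also chosen then) passed the minimum only through the treated library too. None of these genes could have been called lower. FABP2, the intestinal fatty acid binding protein, had 0 counts untreated and 80 treated, which makes it at least 39.2-fold higher. REG4, a secreted lectin of intestinal epithelium, was 113-fold higher, from 0.0610 to 7.35 CPM. CDH17 (liver-intestine cadherin, chromosome 8, 95139394 to 95229531) rested on far more counts and was 7.59-fold higher, from 160 to 1214 CPM. The intestinal transcription factor CDX2 was not called, with a log2 ratio of 0.45, and CEACAM6 stood at -0.56. Of 26 gastric epithelial markers 8 were measured, 4 of them called higher and 2 lower. Their median was 1.44 at percentile 100 (0.58 with no minimum CPM and 2.30 with one of 5 CPM). The other genes of this list and of the intestinal list had under 1 CPM in both pools. MUC5AC of the gastric list, chosen after its value was seen, was measured only through the treated library (0.287 to 3.38 CPM). ANXA10, an annexin of gastric mucosa, was 23.5-fold higher at 78.0 CPM, and CTSE (cathepsin E) had a log2 ratio of 3.55, while SOX2 (-3.11) and GAST (-2.05), both under 3 CPM untreated, were called lower. Membrane mucins had 9 measured members, 3 called higher and 2 lower, with a median of 0.65 at percentile 99.7 and a mean of 1.27. MUC17 went from 4 to 1688 counts, 552-fold higher, and MUC13 from 35.6 to 412 CPM, while MUC16 (CA125) had a log2 ratio of -3.19 and MUC15 one of -2.06. MUC17 and its neighbours MUC3A and MUC12 have similar repeats, so counts split between them are uncertain. Beside these lists, fibroblast markers, whose reads can come from the host, had a median of 0.66 and a mean of 0.25, and myeloid markers had a median of 0.91 that turned to -0.39 with no minimum CPM.

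Squamous epithelial markers were lower as a group. Of 18 measured members, 14 were called lower and 2 higher, with a median log2 ratio of -2.63 at percentile 0. S100A9, a calcium-binding protein of stressed squamous epithelium and myeloid cells, was 55.1-fold lower, from 13.0 to 0.231 CPM. IVL (involucrin), a precursor of the cornified envelope, was 44.8-fold lower, from 174 to 3.88 CPM. The basal keratins KRT5 and KRT14, chosen after their values were seen, had log2 ratios of -5.47 and -4.87, from 159 and 540 CPM untreated, and KRT14 shares sequence with KRT16 and KRT17. The desmocollin DSC3 (2.72) and the kallikrein KLK5 (1.69) went the other way and were called higher. Among 25 genes of epithelial junctions and simple keratins, 2 were called higher and 2 lower, with a median of -0.25 at percentile 0.54 (block-centred -0.05) and a mean of -0.17 at percentile 16.6. KRT20, in neither the intestinal nor the gastric list, went against those lists with a log2 ratio of -4.29, from 145 to 7.41 CPM. CLDN4 had a log2 ratio of -1.10, while CLDN3 stood at 2.09. Host skin and other host tissue markers moved apart beside this list, with 1 of 7 measured members called higher and 2 lower, a median of -0.06 (block-centred 0.01) and percentile 37.4. In that list FLG (filaggrin), also made by squamous epithelium, had a log2 ratio of -5.80, DES (desmin) one of -1.23 and CIDEC, a fat droplet protein, one of 4.48.

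**Figure D2:**
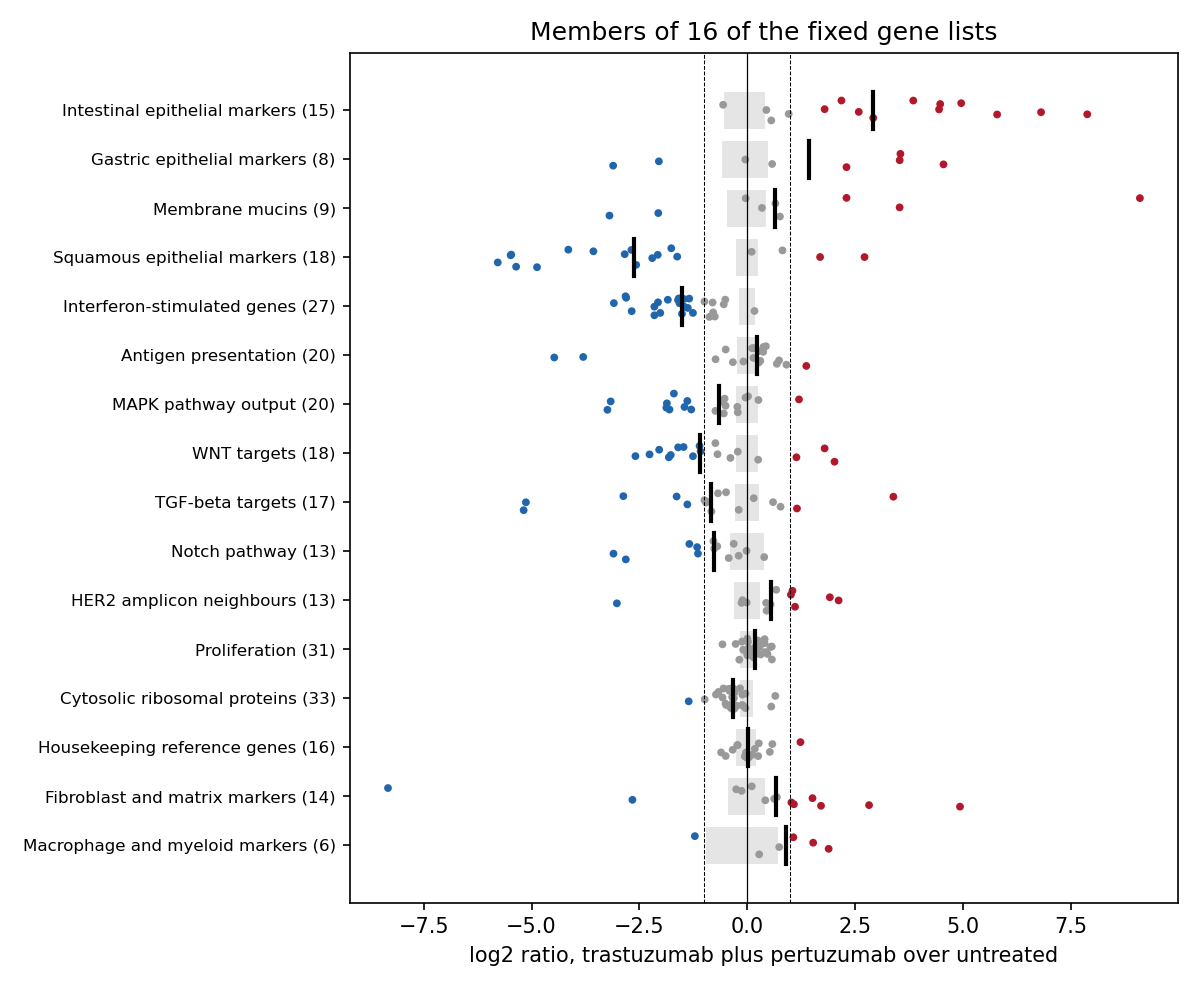
Points are measured members of 16 of the 41 fixed gene lists, with the number of members in brackets and the log2 ratio of treated over untreated on the x axis; red members were called higher and blue members lower, black bars are list medians, and grey boxes hold the central 95% of medians of 10000 random lists matched on expression. Intestinal markers have their median at 2.92, squamous markers at -2.63, interferon-stimulated genes at -1.51 and proliferation genes at 0.19.

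Interferon-stimulated genes were lower nearly throughout. Of 27 measured members, 19 were called lower and 0 higher, with a median log2 ratio of -1.51 at percentile 0, and 26 had a ratio below 0. OAS2, an activator of antiviral RNA decay, was 8.52-fold lower, from 263 to 30.8 CPM, and DDX58, which encodes the RNA sensor RIG-I, was 7.06-fold lower. STAT2 had a log2 ratio of -0.51, and IRF7 was the exception at 0.17 (0.04 to 0.30). DDX58 lies in a part of chromosome 9 whose genes were on the whole lower. Of 20 measured antigen presentation genes, 17 were not called, 1 was higher and 2 were lower. Their median was 0.23 at percentile 97.97, but it turned to -0.33 after centring on blocks, with 12 of the 20 in a region of chromosome 6 that was shifted upwards, and their mean was -0.18. The MHC class II genes HLA-DRA (-4.47) and CD74 (-3.80) were the 2 called lower, HLA-DRB1 (1.37) was called higher, and TAPBP stood at 0.91. Class II genes can come from myeloid and lymphoid host cells. The 4 measured lymphoid markers were all called lower, with a median of -3.25 and a sum of 7.87 CPM untreated, while the 6 measured macrophage and myeloid markers had 3 members called higher and 1 lower, with a median of 0.91 at percentile 99.1 that turned to -0.39 with no minimum CPM, and a mean of 0.72 at percentile 93.7. Among NF-kB and chemokine genes, 2 of 16 were called higher and 5 lower, with a median of -0.48 at percentile 0.48 (block-centred -0.32) and a mean of -0.94. CXCL5, a neutrophil chemokine, had a log2 ratio of -6.16 and the complement component C3 one of -4.75, while CCL15 (2.82) and CCL28 (1.83) were called higher. Of 20 genes of complement control and Fc-effector susceptibility, 0 were called higher and 4 lower, with a median of -0.19 at percentile 10.9. CD274, which encodes PD-L1, had a log2 ratio of -2.40 and the NKG2D ligand RAET1E one of -3.61, while MICA (0.85) and HLA-G (0.76) were not called.

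Transcripts that ERK signalling induces were lower as a group. Of 20 measured members of the MAPK output list, 9 were called lower and 1 higher, with a median log2 ratio of -0.66 at percentile 0.01 (block-centred -0.93). PHLDA1 was 8.97-fold lower, from 805 to 89.7 CPM, and EPHA4 had a log2 ratio of -3.24, while the feedback inhibitor SPRY2 was 2.30-fold higher. Immediate early genes as a whole lay near 0, with 2 of 22 called higher and 6 lower, a median of -0.04 (block-centred 0.05) and percentile 37.0. EGR2 had a log2 ratio of -3.13 and IER2 one of -1.71, while CTGF (1.70) and ATF3 (1.26) were called higher. IER2 lies in a block of chromosome 19 whose median was -0.74. FOXO targets, which are induced when AKT signalling is low, included 2 of 19 called higher and 3 lower, with a median of -0.06 at percentile 27.0. PDK4 (1.97) and SESN1 (1.52) were called higher, and TRIB2 (-4.81) and SESN3 (-3.18) lower. None of the 31 proliferation genes was called, and their median was 0.19 at percentile 98.7 (block-centred 0.10), with a mean of 0.16 at percentile 94.3. MYBL2 and UBE2C both stood at 0.57, CCNE1 at -0.57 and CCNB1 at -0.27. Of 11 measured replication-dependent histone genes, 0 were called higher and 4 lower, with a median of -0.48 at percentile 8.19, a block-centred median of -1.14 and a mean of -0.76. HIST1H4H had a log2 ratio of -2.18 and HIST2H2BE one of -1.81, while HIST1H2BC stood at 0.75 without a call. The RNAs of these histone genes mostly lack a poly(A) tail, so their counts from an mRNA kit may not follow their expression.

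WNT, TGF-beta and Notch genes had lower medians in the treated pool. Among 18 measured WNT targets, 10 were called lower and 3 higher, with a median log2 ratio of -1.09 at percentile 0. SP5 (-2.59) and LEF1 (-2.26), both activated by beta-catenin, were called lower, while the WNT inhibitor DKK1 (2.03) and the stem cell receptor LGR5 (1.80) were called higher. Of 17 TGF-beta genes, 5 were called lower and 2 higher, with a median of -0.83 at percentile 0 (block-centred -0.63). TGFBI, a secreted matrix protein, was 35.1-fold lower, from 599 to 17.1 CPM, and the ligand TGFB2 was 36.3-fold lower, while the ligand TGFB1 was called higher with a log2 ratio of 1.15. The Notch list had 0 of 13 members called higher and 5 lower, with a median of -0.76 at percentile 0.17 and a mean of -0.95 at percentile 5.05. NOTCH3 had a log2 ratio of -2.81 and the target HEY2 one of -3.10. NOTCH3 lies in a block of chromosome 19 whose median was -0.83. YAP targets were mixed, with 4 of 18 called higher and 2 lower, a median of 0.07 (percentile 71.0) and a mean of -0.04. AXL (1.95) and DLC1 (1.93, from 0.401 to 1.54 CPM) were called higher and ANKRD1 (-1.67) lower. Mesenchymal genes were mixed too, with 3 of 16 called higher and 4 lower, a median of -0.05 (block-centred 0.04) and percentile 36.2. VIM (vimentin) had a log2 ratio of 1.11 and FN1 (fibronectin) one of -2.66.

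Of 20 NRF2 targets, 3 were called higher and 0 lower, with a median log2 ratio of 0.37 at percentile 99.8 (block-centred 0.20). AKR1B10, an aldo-keto reductase with close paralogs, was 15.3-fold higher, ABCC2 stood at 1.47, and AKR1C2 (-0.77) was not called. Cholesterol synthesis genes had a median of 0.21 at percentile 98.3 and a mean of 0.12 at percentile 85.7, with 1 of 24 called higher and 2 lower. STARD4, a sterol transfer protein, was among the genes called lower with a log2 ratio of -1.32, and HSD17B7 stood at 0.74 without a call. Fatty acid synthesis genes had 1 of 12 called higher and 4 lower, with a median of -0.28 at percentile 4.58, a block-centred median of -0.47 and a mean of -0.66. SCD had a log2 ratio of 1.10, FADS1 one of -3.17 and ELOVL6 one of -2.43. Hypoxia genes had 3 of 21 called higher and 0 lower, with a median of 0.13 at percentile 90.4 and a mean of 0.38, the mean beyond the central 95% of random lists. EGLN3, a prolyl hydroxylase, was 8.34-fold higher, from 179 to 1491 CPM, and VEGFA had a log2 ratio of 1.32. EGLN3 lies in a block of chromosome 14 whose median was 1.36. The unfolded protein response list had 3 of 22 called higher and 0 lower (median 0.15, percentile 90.3, block-centred 0.27, with a mean of 0.35 beyond the central 95%). Among those called higher were DDIT3, which encodes CHOP, at 1.06 and CREB3L1 at 1.81 (0.348 to 1.23 CPM). Of 21 p53 targets, 2 were called higher and 0 lower (median 0.18, percentile 92.2), and CDKN1A, which encodes p21, went from 44.7 to 103 CPM. CDKN1A lies in a block of chromosome 6 whose median was 0.45. Apoptosis regulators had a median of 0.00 at percentile 50.5 and a mean of -0.14, with 0 of 17 called higher and 1 lower, PMAIP1 (NOXA) at -2.41. Drug transporters had 4 of 11 called higher and 2 lower (median 0.26, percentile 90.9, but -0.18 with no minimum CPM or one of 5 CPM). ABCA1 stood at 3.02 and ABCA3 at -1.43. ABCG2 (BCRP) stood at 1.94 but near the minimum, from 0.401 to 1.55 CPM. Angiogenic factors had 3 of 15 called higher and 3 lower, with a median of 0.71 at percentile 99.99 (block-centred 0.55) but a mean of 0.10 at percentile 76.2. PGF (2.68, from 0.375 to 2.42 CPM) and EFNA1 (1.72) were called higher, and FGF2, from 23.6 to 0.512 CPM, was called lower at -5.51.

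Genes of basic cell functions lay close to equality. Oxidative phosphorylation genes encoded in the nucleus had 1 of 27 called higher and 0 lower, with a median of 0.08 at percentile 83.2 (block-centred 0.04), and the called gene was NDUFA2 (2.08). None of the 13 genes of the list of mitochondrially encoded genes was measured. Housekeeping reference genes had 1 of 16 called higher, GUSB at 1.24, and a median of 0.01 at percentile 60.1. Cytosolic ribosomal protein genes had 0 of 33 called higher and 1 lower, RPS28 at -1.36, and their median of -0.33 lay at percentile 0.03, with 31 members below 0. RPL11 had a log2 ratio of 0.65 and RPS6 one of -0.98, and RPL11, RPS6 and RPS28 lie in shifted regions of chromosomes 1, 9 and 19, each moved in the direction of its region. The most abundant rows in the untreated pool were EEF1A1 at 8265 CPM, ERBB2, KRT8 at 5237 CPM, the ribosomal RNA precursor RNA45S5 at 5026 CPM and RPL19 at 4850 CPM. In the treated pool ERBB2 stood first, followed by EEF1A1 at 8195 CPM, RNA45S5 at 6950 CPM, RPL19 at 3821 CPM and ACTB at 3525 CPM.

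Markers of other cell types that a xenograft holds moved in different directions. Of 14 measured fibroblast and matrix markers, 6 were called higher and 2 lower, with a median log2 ratio of 0.66 at percentile 99.7 and a mean of 0.25 at percentile 88.2. LUM (lumican), with 5 counts untreated and 114 treated, had a log2 ratio of 4.94 and TAGLN (transgelin) one of 2.83. FN1 stood at -2.66 and COL5A1, with 2 treated counts, at -8.33 (-11.70 to -6.79). Among the myeloid markers CD68 had a log2 ratio of 1.89, SPI1 one of 1.53 and CTSS (cathepsin S) one of -1.21. Endothelial markers had 1 of 5 measured members called higher and 2 lower, with a median of -0.48 at percentile 28.0 that turned to 0.23 with a minimum of 5 CPM. EGFL7 had a log2 ratio of 1.09 and VWF one of -2.83, and ROBO4, with 0 treated counts, was at least 82.3-fold lower. The median of the 4 lymphoid markers lay at percentile 5.26, with CD79A at -4.56 and CD8A at -3.73. With the skin, muscle, fat and blood markers, the 36 measured genes of the host lists summed to 524 CPM untreated and 609 CPM treated. Cancer cells make some of these transcripts as well, and the sources used here do not say how mouse reads were treated.

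The 12 genes with the largest positive ratios among called genes of at least 10 CPM were at least 14.4-fold higher. MMP1, an interstitial collagenase, was 82.6-fold higher, with 16 counts untreated and 926 treated. SPINK1, a secreted trypsin inhibitor, was 40.0-fold higher at 89.7 CPM. IHH (Indian hedgehog) was 37.9-fold higher, PRAP1 25.9-fold, MYO7B of the brush border 21.4-fold, TM4SF4 15.7-fold, and the gut lectin LGALS4 14.4-fold at 342 CPM. UGT2B15 was 24.6-fold higher, with close paralogs that can share its reads. MUC17, ANXA10 and AKR1B10 were also among the 12. ARL2-SNX15, a readthrough transcript on chromosome 11 (64781585 to 64808044) that overlaps ARL2 and SNX15, had 0 counts untreated and 851 treated, and its counts are uncertain for that reason.

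The 12 genes with the smallest ratios among called genes of at least 10 CPM had ratios no larger than that of HEPHL1, which was 106-fold lower. KLK14, a kallikrein protease of skin, was 491-fold lower, from 66.0 to 0.128 CPM. GJA1 (connexin 43) was 168-fold lower, from 12474 to 50 counts. SERPINB3, which shares reads with SERPINB4, was 267-fold lower and had 5 treated counts. HEPHL1 encodes a copper-binding ferroxidase. VSNL1 was 109-fold lower, TPRXL 121-fold and CCDC22 194-fold. ZC2HC1A had 1929 counts untreated and 0 treated, which makes it at least 437-fold lower. CACNA1H and ZNF175 had 2 treated counts each, with log2 ratios of -9.08 (-12.45 to -7.55) and -8.40 (-11.77 to -6.87). FLJ43879 had 3 treated counts and a log2 ratio of -8.37 (-10.87 to -7.04), and COL5A1, described with the fibroblast markers, completes the 12. In all, 7 genes had at least 10 CPM untreated and under 0.1 CPM treated, and 2 the reverse.

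Neighbouring genes were shifted together in several chromosome regions. Genes of chromosome 9 from 14511 to 33573001 (hg19) had a median log2 ratio of -0.94, a ratio of 0.523, and 90.7% of its 75 genes were lower in the treated pool. Genes of chromosome 19 from 7701987 to 10580307 had the same median of -0.94, with 94.0% lower. Higher in the treated pool were regions of chromosome 1 (16767167 to 24513765, median 0.81), chromosome 4 (53179 to 10459032, median 0.74, and 25162294 to 48908845, median 0.66) and chromosome 6 (29794756 to 36304662, median 0.76, which holds the HLA genes). These are the runs of at least 2 adjacent blocks of 25 expressed genes whose medians lay outside the range of 100 random gene orders, -0.77 to 0.61. Of 532 blocks, 21 lay above that range and 10 below. Block medians had an SD of 0.27, against a mean of 0.13 in random orders. The 6 runs hold 475 genes, 3.57% of those in blocks, and 6.58% of the called genes. Besides the 3 ribosomal protein genes, FGFR3, DDX58, CD274, MUC16, TAPBP, MICA and the HLA genes named here lie in them. Gene families lie side by side, as the HLA genes do, so neighbours can also share regulation or reads.

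**Figure D3:**
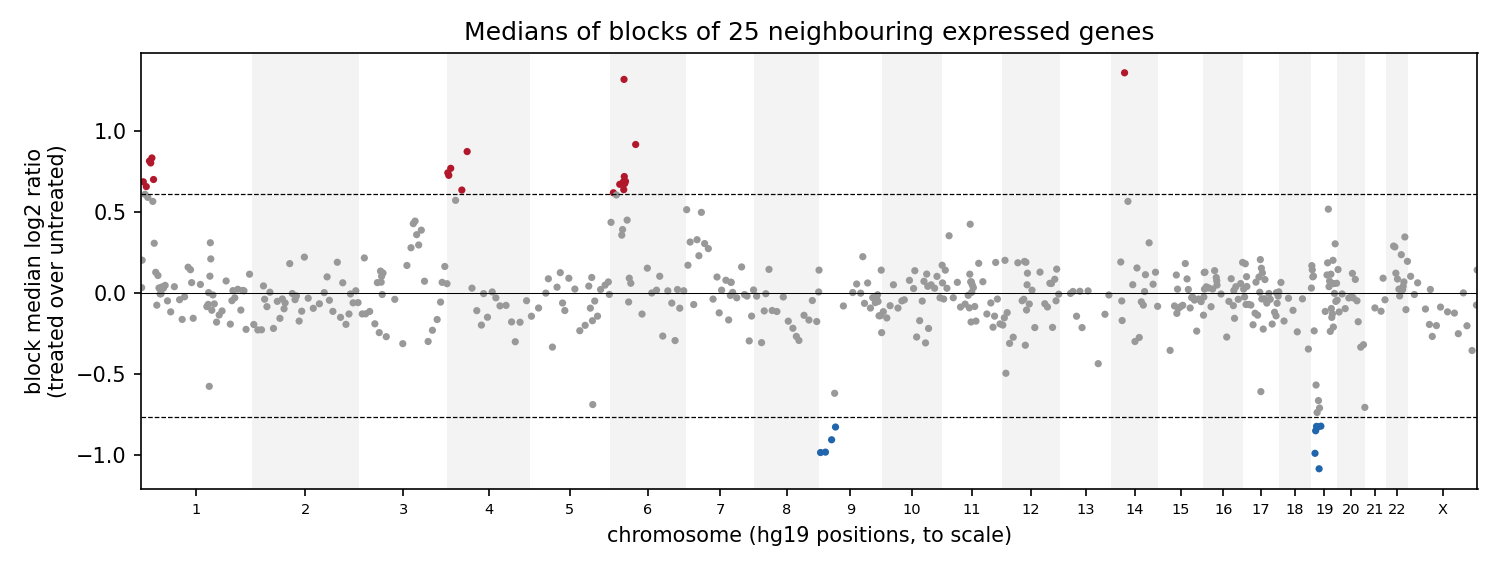
Each point is the median log2 ratio (y axis, treated over untreated) of 1 of 532 blocks of 25 neighbouring expressed genes, at its hg19 position along the chromosomes on the x axis, to scale. Dashed lines mark the lowest and highest block medians of 100 random gene orders, -0.77 and 0.61, with red points above and blue points below them, and adjacent shifted blocks stand on chromosomes 1, 4, 6, 9 and 19.

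The authors' deposited table also compares the 2 libraries gene by gene. Of the genes in the authors' deposited table, 929 had an adjusted p under 0.05, 151 of them higher and 778 lower in the treated library. Of these 929 genes in the authors' deposited table, 531 were also called by the rule of size, and 398 had under 1 CPM in both libraries. MUC17, KLK14 and CD74 were among the 929 genes in the authors' deposited table. CDH17, OAS2, DDX58, PHLDA1, NOTCH3, SP5, FGFR3, ERBB2, ERBB3 and EGFR were not. Log2 ratios correlated between the authors' deposited table and the values here with a Pearson r of 0.994 across measured genes, which are not independent replicates. These p-values come from 1 library per group, so they compare the 2 libraries and rest on an assumed spread between replicates.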

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

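No paired analysis was possible because each group has 1 library, and no library could be left out in turn. Alternatives chosen only after the data were seen are thinning, leaving out chromosome runs or repeated rows, the authors' FPKM, centring on chromosome blocks and the assumed dispersions. Of 359 list values under an alternative, 343 kept their sign, and the 16 that did not were under none of the other scalings or added counts. In all, 353 lay within the 95% binomial interval of the list's median over its members without reversing a list beyond the random range, but that interval is wide for small lists and let the histone median move from -0.48 to -1.14 after centring on blocks. None of 885 values of 177 named genes reversed a called gene. Under the other scalings 1131 to 1193 genes were higher and 1540 to 1604 lower, with a shift of at most 0.04 on the log2 scale. With the untreated counts thinned to the treated total 1118 were higher and 1600 lower, of which 1089 and 1583 were also called with all counts, so the difference in depth moved few calls.

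Counts of calls moved with their own thresholds. With no minimum CPM 1788 genes were higher and 2953 lower, with 5 CPM 714 and 1037, with a 4-fold threshold 315 and 804, and with a 1.5-fold threshold 2285 and 2533. The lower share of calls was 71.8% at 4-fold and 52.6% at 1.5-fold. The intestinal median was 0.93 lower with a minimum of 5 CPM, the largest move of a list median under that setting. The ERBB receptor median was 0.58 with upper-quartile scaling. The ribosomal protein median was -0.29 with upper-quartile scaling and -0.28 after centring on blocks. The antigen presentation median of 0.23 reversed to -0.18 as a mean, which HLA-DRA (-4.47) and CD74 (-3.80) pull down, and to -0.33 after centring on blocks, and 12 of its 20 members lie in the chromosome 6 run. The macrophage and myeloid median reversed to -0.39 with no minimum CPM, which adds genes of few counts. By the mean in place of the median 9 lists fell back within the central 95% of random lists, namely ERBB ligands, proliferation, epithelial junction, antigen presentation, cholesterol, Notch, angiogenic, fibroblast and myeloid genes, and 2 moved beyond it, hypoxia and the unfolded protein response; the cause was not tested. Other lists that changed sign were ERBB receptors, other receptor tyrosine kinases, YAP targets and apoptosis regulators by the mean, drug transporters and endothelial, mesenchymal and apoptosis genes under another minimum CPM, and immediate early, mesenchymal, apoptosis and skin, muscle, fat and blood genes after centring on blocks. The count of 929 genes in the authors' deposited table compares with 1924 at an assumed dispersion of 0.1 and 102 at 0.4, so it is set by a spread that these libraries cannot supply. The totals without mitochondrially encoded genes were not run.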

Other observations

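Grouping genes by the stem of their symbols, a step chosen after the data were seen, gave 85 families of at least 15 measured genes, of which 12 had medians outside the central 95% of random lists. Keratins were lower in the treated pool, with 13 of 21 KRT genes called lower and 0 higher, and a median log2 ratio of -1.49. This largely repeats earlier results. Of the lower genes, KRT5, KRT6A, KRT6B, KRT13, KRT14, KRT16 and KRT17 are in the squamous list and KRT20 is in the junction list. KRT23 went from 1889 to 263 CPM, outside the squamous and junction lists, while KRT7 stood at 0.42 and KRT10 at 0.09. Annexins went the other way, with 7 of 17 rows called higher and 1 lower and a median of 0.78, in a family that includes pseudogenes of ANXA2. Besides ANXA10, ANXA13 of intestinal epithelium had a log2 ratio of 3.06 and ANXA4 one of 1.47, and ANXA1, an annexin abundant in squamous epithelium, one of -1.15. Histone genes had 19 of 33 rows called lower and 1 higher, with a median of -1.24. Without repeated rows and rows that share both counts it was -0.90 over 27 genes. The limit of an mRNA kit stated for replication-dependent histone genes applies here too. Interleukins and their receptors had 8 of 31 called higher and 4 lower, with IL2RG at 2.73, IL32 at 2.34 and IL22RA1, the receptor of IL-22 on gut epithelium, at 1.80. Genes named in this paragraph were chosen after their values were seen.

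The tests of mouse skin, of a single unusual tumour, of fewer host cells and of chance order, the genes between those that chose a run, and the wider stretches of shifted blocks, were chosen only after the results they bear on were seen.

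Intestinal markers were higher and squamous markers lower in the treated pool. The counts of KRT1, KRT2, KRT10 and LOR, abundant in epidermis, were 2.49% of those of KRT5 and KRT14 in the untreated pool. That was 17.4 against 699 CPM, with an upper counting bound of 2.61%, and KRT10 alone had 17.3 CPM. These values go against mouse skin there only if mouse reads of these genes were counted alike. The treatment of mouse reads is not given, and FLG, a host skin marker, fell with the squamous list from 11.8 to 0.205 CPM. Mouse skin in the untreated pool therefore stays open. Chromosome-scale shifts are argued against as the whole cause, since after each gene's ratio was centred on its 25-gene block the intestinal median was 3.19 and the squamous median -2.42. A single unusual tumour in 1 of the pools is argued against as the whole cause, provided the remaining tumours were alike. Equal mixing of 5 tumours then leaves at least 4/5 of each transcript, while the squamous median was -2.63 and the intestinal median 2.92, in opposite directions. Whether the remaining tumours were alike was not measured. The treatment, which the design names, stays open and was not tested apart from other differences between the pools, such as an unusual tumour in each.

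Interferon-stimulated genes were lower in the treated pool. Chromosome-scale shifts are argued against as the whole cause, with a list median of -1.54 after centring on blocks. Fewer host cells in the treated pool cannot be told apart from a change in the cancer cells, because the summed CPM of 2 host lists was higher and that of 3 lower (524 untreated and 609 treated in all, against a drop of 3011 CPM of the interferon list), cancer cells make some of these transcripts, and the treatment of mouse reads is not given. Genes of immune cells went both ways. The 4 lymphoid markers were all called lower (7.87 CPM untreated in sum), and HLA-DRA and CD74 together stood at 45.4 and 2.97 CPM. Myeloid markers stood at 122 and 137 CPM in sum, CD68 (1.89) and SPI1 (1.53) among them. HLA-DRB1 stood at 1.37, but it lies with HLA-DRA in a block of chromosome 6 whose median was 0.72. The treatment and other differences between the pools stay open and were not tested.

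Neighbouring genes were shifted together over long stretches, and with the central 99% of random block medians as limits, 7 stretches held 1200 genes, among them chromosome 9 up to 37.5 Mb (median ratio 0.548), chromosome 19 from 7.70 to 24.3 Mb (0.567, with 93.2% of genes lower), chromosome 1 from 2.34 to 28.1 Mb (1.62), chromosome 4 up to 48.9 Mb (1.62) and chromosome 6 from 0.292 to 41.2 Mb (1.55). Chance order is argued against, since 61 blocks lay beyond the central 99% of random block medians and at most 11 did in 100 random orders, and GC content is too, since 31 of the 31 blocks beyond the full random range stayed beyond it after ratios were centred in 20 bins of transcript GC. When runs were chosen on every second gene, the genes between them had median shifts in the run's direction of 0.73 to 0.79 over both ways of splitting and both levels of expression, with 89.3% and 89.4% of 345 and 369 genes in that direction. A difference in gene dosage between the pools, shared regulation of neighbouring genes and the treatment stay open, since these values do not separate them and DNA was not analysed here.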
